A study of Homo sapiens with 8 samples.

How the data were processed

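RNA of 4 MCF10A clones was sequenced, with 2 libraries per clone. Per the labels' protocols, total RNA was taken with an RNeasy kit and libraries were made with the Illumina TruSeq RNA kit v3. Per the submitters' processing notes, the tools were CASAVA, TopHat2 2.0.10, Cufflinks and HTSeq and the genome build was GRCh38, and the role of each tool is not given in the sources used here. The deposited junction values are raw counts of spliced reads per junction and library, with no normalization and no strand. The deposited transcript files hold FPKM values per annotated or assembled transcript, which Cufflinks computed per library, per the file headers. FPKM is scaled by transcript length and library size and carries no read count. An exact 0 can be a failed estimate, since 1399 of the 11428 genes tested were at 0 in at least 1 library and 1017 of these exceeded 5 FPKM in another.

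Groups came from the genotype labels, titles and design text. The labels conflict in places: 1 library is titled R702R2 where the design text names only R702R1, and the TWT1 libraries carry the genotype label R702R. Both were kept in the wild-type group, as the design text has it. The libraries of a clone share an index and differ in lane by their file names, so they were not taken as separate cultures, and the clone was the unit. Junction reads of a clone's libraries were summed and log2 FPKM averaged, giving 2 clones against 2. Whether libraries of a clone differ was tested by chi-square over junctions with at least 20 reads.

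Junctions were matched to the splice sites of GENCODE release 29 on GRCh38, which gave 1 strand to 97.5% of junction reads, while 2.46% had no annotated site and were left out. Introns of 50 nt to 500 kb were kept. For each donor the acceptor with most wild-type reads was the reference. Alternative acceptors needed 10 reads and donors 10 reads in each clone. Differential use was tested with edgeR 4.0.16 (TMM, glmQLFit, diffSpliceDGE), called at a Benjamini-Hochberg adjusted p under 0.05 and a change of at least 5 percentage points. The class 10 to 30 nt upstream was compared with other acceptors by a two-sided Fisher's exact test. Intervals of shares are exact 95% binomial intervals, and these and the floor of 3 reads cover counting error only.

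Gene FPKM was the sum over transcripts. Genes with a mean of at least 1 FPKM were tested with limma 3.58.1 (trend) on log2(FPKM + 1), called at an adjusted p under 0.05 and a log2 fold change of at least 1 in size. Fold changes on this scale understate the change of low genes. Spliced reads summed per gene were tested with edgeR's quasi-likelihood test at the same thresholds. Spliced reads per gene count junctions only, so genes without introns have no value. A junction shared by overlapping genes was counted for only 1 of them, protein-coding genes first. Gene lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry. Random lists matched on expression numbered 10000. R 4.3.3 was used.

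The tests, the gene lists and the naming rule were fixed before the data were examined. The rule named SF3B1, the 12 highest and 12 lowest called protein-coding genes, called members of the serine and complex III lists, PHGDH, PSAT1, PSPH, SHMT2 and UQCC1, and 2 to 4 members with the largest changes in each other list. For splicing it named the 15 largest rises and 5 largest falls in acceptor use, the 5 largest donor changes and each tested acceptor 10 to 30 nt upstream in the reported SF3B1 genes. Some genes that the rule names are not reported here. Genes outside the rule are said to have been chosen after their values were seen, and this also holds for the list members named in glycolysis and complex III. The lists were serine synthesis and one-carbon metabolism, complex III, complex I, mitochondrially encoded mRNAs, TCA cycle, glycolysis, ATF4 response, reported SF3B1 genes, U2 factors, nonsense-mediated decay, p53 targets, proliferation, NF-kB targets, interferon-stimulated genes, cholesterol synthesis, heme and iron handling, and basal, luminal, mesenchymal and hematopoietic markers.

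The tests were run on simulated data with 200 features changed by 2 on the log2 scale. For limma over 10029 genes 98% were recovered with 0 false calls, and for edgeR over 12795 genes 100% with 2 false calls. For acceptors, over 36554 sites, 45.5% were recovered with 0 false calls, and for donors, over 33882 sites, 44% with 1. Changed acceptors and donors were drawn only from sites with enough reads and a moderate mean use, so their rates do not cover sites rarely used in wild type. False calls at alternatives of a changed site were not counted. The simulated spread was assumed and not estimated from the clones. The limma genes were those above 0 in all 8 libraries, so these rates do not cover failed FPKM estimates at 0. Alternatives were other pseudocounts, filters and thresholds, quantile normalization, DESeq2 1.42.0, limma on log2 odds, the 8 libraries as replicates with and without a block, the libraries of each replicate number alone, reference sites set by mean use over all clones, and each clone left out. The genome sequence was not used here, so splice site sequences were not analysed here.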

Results

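RNA sequencing was compared between cells with and without a hotspot change of SF3B1, the subunit of the U2 small nuclear ribonucleoprotein that contacts the intron branch point. The cells were clones of MCF10A, a non-tumorigenic human mammary epithelial line. Clones K700E1 and K700E2 carried the K700E change, clone R702R1 carried a silent change at a nearby codon, and clone TWT1 was wild type. Each clone had 2 libraries, so that 4 libraries of 2 K700E clones stood against 4 libraries of 2 wild-type clones. Spliced reads numbered 28890517 and 28738408 in the K700E1 libraries, 26133530 and 26193071 in K700E2, 28290280 and 28013206 in R702R1, and 35803669 and 35639521 in TWT1. The labels do not say that the libraries of a clone came from separate cultures, so the clone was the replicate (n = 2 per genotype) and p-values measure only the spread between clones. Over junctions with at least 20 reads, the libraries of a clone gave a chi-square of 1.98 to 2.12 per degree of freedom, against 3.12 and 3.15 for K700E1 with K700E2 and 7.35 and 7.39 for R702R1 with TWT1. Same-clone libraries therefore differed by more than simple counting noise but by less than different clones of one genotype.

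The first question was which 3' splice sites (acceptors) the K700E cells used differently from the same donors. K700E cells spliced to many acceptors a short way upstream of the usual one. In TMEM14C, a mitochondrial inner membrane protein of heme synthesis, an acceptor 14 nt upstream (GRCh38 chromosome 6, intron 10723242 to 10724555) took 69.3% ± 1.22 of donor reads in K700E clones and 3.77% ± 0.202 in wild-type clones (SD, n = 2 each; edgeR adjusted p = 2.82e-08). In MAP3K7, which encodes the kinase TAK1, an unannotated acceptor 20 nt upstream (chromosome 6, intron 90560235 to 90561621, minus strand) took 69.3% ± 5.28 against 6.51% ± 0.85 (edgeR adjusted p = 0.00238). In DYNLL1, a dynein light chain, an acceptor 14 nt upstream (chromosome 12, intron 120496217 to 120496401) took 62.1% ± 1.74 against 7.74% ± 0.214 (edgeR adjusted p = 0.00011).

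Of 36554 alternative acceptors at 26907 donors, edgeR called 243 as changed by at least 5 percentage points, 233 with higher and 10 with lower use in K700E. Acceptors 10 to 30 nt upstream of the reference acceptor made up 143 of the 233, in 138 genes, and none of this class was called lower. The 143 were 9.63% of the 1485 tested acceptors of the class, and the 90 others called higher were 0.257% of the 35069 tested acceptors outside it (odds ratio 41.4, two-sided Fisher's exact p = 7.55e-138, with acceptors not independent replicates). Among the 143, 106 acceptors were absent from the annotation, the median distance was 18 nt, and 125 lay 12 to 21 nt upstream. Their median use was 14.8% in K700E and 0.223% in wild-type clones. Among other classes, 17 of 885 tested acceptors were called higher at 31 to 100 nt upstream (1.92%). The counts were 31 of 6618 at 1 to 100 nt downstream (0.468%) and 2 of 402 at 1 to 9 nt upstream (0.498%). Farther away, 40 of 27164 were called higher (0.147%). The count of changed acceptors depended on having both clones of each genotype: without K700E1 it was 36, without K700E2 30, without R702R1 159 and without TWT1 138. DESeq2 with an interaction called 656, and limma on the log2 odds called 0, with 3596 acceptors at an unadjusted p under 0.05. The reference was the acceptor with most wild-type reads, which itself favours calls of higher use. With the reference set by mean use over all clones, a setting added after seeing the data, edgeR called 231 higher and 18 lower, 239 of them shared, with 140 higher and 1 lower in the class 10 to 30 nt upstream.

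**Figure D1:**
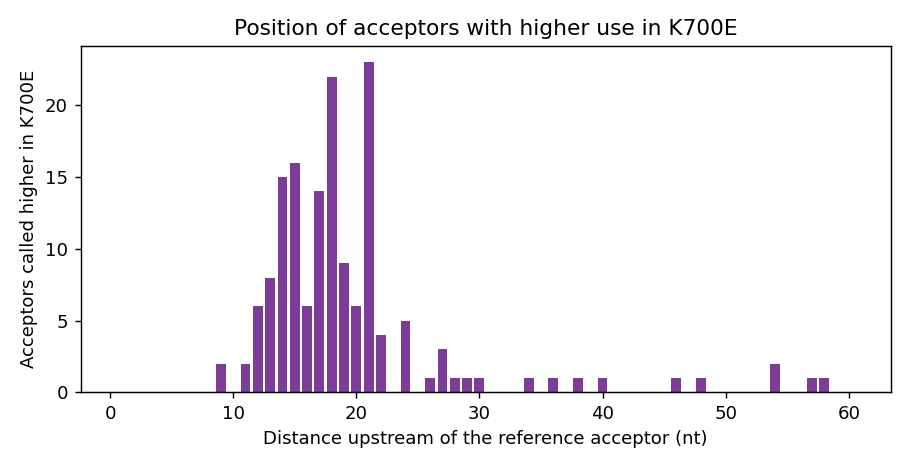
Number of acceptors called with higher use in K700E (y axis) at each distance upstream of the reference acceptor in nt (x axis, 1 to 60). The highest bars are at 21 and 18 nt, and 125 of the 143 acceptors of the 10 to 30 nt class lie 12 to 21 nt upstream.

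The 15 largest rises were led by GEN1, a Holliday junction resolvase, where an annotated acceptor 17 nt upstream (chromosome 2, intron 17754346 to 17759911) went from 7.13% ± 3.8 to 96.8% ± 4.54 (SD, n = 2; edgeR adjusted p = 0.0189). MFSD9 rose by 80.7 percentage points at an acceptor 17 nt upstream, ZNF548 by 73.2 at 17 nt, CCDC66 by 66.2 at 18 nt, SH3D19 by 61.7 at 19 nt and ARMC9 by 57.1 at 26 nt. The lncRNA VPS9D1-AS1 rose by 65.8 points at 15 nt, on 22 to 39 donor reads per clone. In ZNF548 and ARMC9 the acceptor had 0 reads in both wild-type clones. Rises of other classes in this top group were MTERF2 (80.7 points, 10 nt downstream), JMY (60.5 points, 123 nt downstream) and ZC3H11A (56.5 points, 388 nt upstream). The largest fall was in ECT2, a RhoA exchange factor of cytokinesis, where the acceptor of intron 172755375 to 172756982 on chromosome 3 fell from 49.0% ± 2.7 to 9.08% ± 0.0717 (edgeR adjusted p = 2.83e-05). BCL2L1, the gene of Bcl-xL, fell from 45.6% ± 4.23 to 6.71% ± 4.26 at an acceptor 18 nt downstream (edgeR adjusted p = 0.0474). NBPF12, STAG3L5P-PVRIG2P-PILRB and ZDHHC16 fell by 28.95, 27.4 and 24.6 points. Shares at a donor sum to the whole, so each fall means a gain at other acceptors of that donor. The ZDHHC16 fall was at the same donor as its rise of 58.0 points at an acceptor 21 nt upstream. NBPF12 belongs to a family of near-identical copies, so its reads are uncertain.

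Genes known from earlier work on SF3B1 K700E were asked for by a list fixed before the data were examined. Of its 25 genes, 14 had a tested acceptor 10 to 30 nt upstream and 12 had one called higher. Of the 15 such acceptors tested, 12 were called over all acceptors and 13 when adjusted over the list alone. ENOSF1 rose by 68.0 points, GCC2 by 73.8, ZDHHC16 by 58.0, TTI1 by 43.5, DLST by 41.5, DPH5 by 36.7, SERBP1 by 36.4 and THOC1 by 35.9, and SLC3A2 went from 0.332% to 11.4%. PPP2R5A, a regulatory subunit of protein phosphatase 2A, had 25.9% ± 0.95 against 0.83% ± 1.17 and missed the threshold (edgeR adjusted p = 0.0569). FXYD5 (0.906 points, edgeR adjusted p = 0.809) and a second SERBP1 acceptor (0.618 points, edgeR adjusted p = 0.346) were not called. UQCC1, an assembly factor of respiratory complex III, had no tested acceptor of this class, but 2 acceptors of 1 donor farther away rose by 34.7 and 25.6 points on 43 to 76 K700E donor reads per clone. CRNDE, BRD9 and ANKHD1 likewise rose at acceptors of other classes, by 56.2, 51.7 and 45.1 points.

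**Figure D2:**
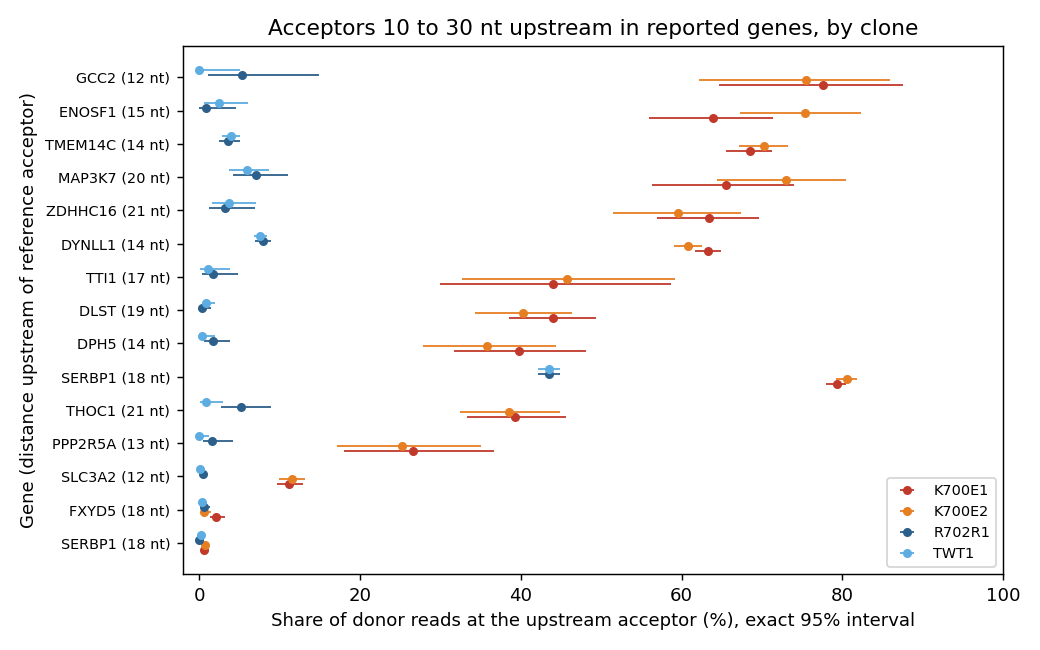
Share of donor reads (x axis, %) at each tested acceptor 10 to 30 nt upstream in the reported genes (y axis), 1 point per clone with its exact 95% binomial interval, which covers counting error only. K700E1 and K700E2 lie to the right of R702R1 and TWT1 at each acceptor, but at FXYD5, with 0.667% in K700E2 and 0.626% in R702R1, the intervals overlap.

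Far fewer donors than acceptors were called. Among 33882 alternative donors, edgeR called 9, all with higher use in K700E and all farther than 100 nt from the reference donor, and none of the 675 donors 10 to 30 nt upstream. They were led by ECT2 (90.4% ± 0.0802 against 49.3% ± 2.42, edgeR adjusted p = 0.0433), DLST (39.0% against 4.66%), TMEM214 (37.3% against 4.53%), NOL9 (24.2% against 0.716%) and SNRPN (25.95% against 2.79%). All 9 genes but TMEM214 and TYW3 also had a called acceptor, and these donor calls are not separate events. In DLST the same junction was also among the called acceptors. In ECT2 the donor ends the exon that is skipped by the junction with the largest fall. In NOL9, SNRPN, TAF2, ATP5F1C and COL4A1 the donor lies a short way past a called acceptor, as the ends of 1 exon would. The count was 1 without K700E1, 1 without K700E2 and 16 without R702R1. DESeq2 with an interaction called 122, and limma on the log2 odds called 0, with 2404 donors at an unadjusted p under 0.05. With the reference donor set by mean use over all clones, edgeR called 8 higher and 1 lower, and the ECT2 donor became the reference.

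Summed over donors, unannotated acceptors 10 to 30 nt upstream took 0.0912% of donor reads in K700E1 (exact 95% interval 0.0901 to 0.0924) and 0.0926% in K700E2 (0.0913 to 0.0938). In R702R1 they took 0.0254% (0.0248 to 0.026) and in TWT1 0.0282% (0.0276 to 0.0288). The genotype means were 0.0919% ± 0.00093 and 0.0268% ± 0.00198 (SD, n = 2), a ratio of 3.43, and the 4 K700E libraries all lay above the 4 wild-type libraries. An exact permutation test of 2 clones against 2 cannot go below p = 0.333, so no p-value is given.

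**Figure D3:**
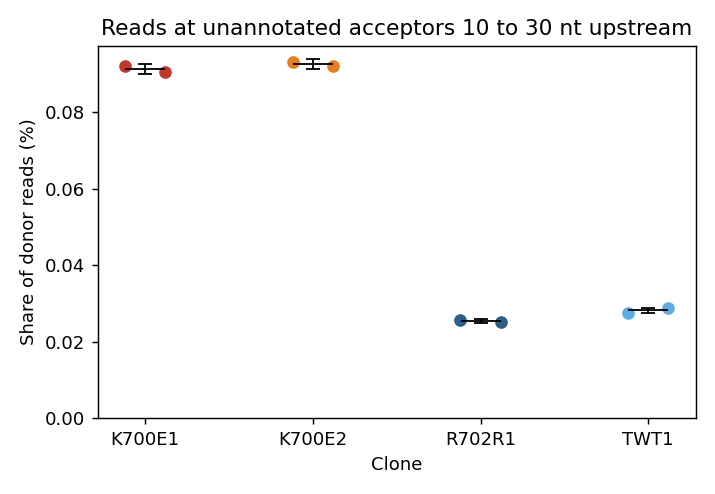
Share of donor reads (y axis, %) at unannotated acceptors 10 to 30 nt upstream, by clone (x axis). Points are the 2 libraries of a clone, and the bar is the clone's share with its exact 95% interval: both K700E clones lie near 0.092% and both wild-type clones below 0.029%.

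Gene expression was compared next, starting with the altered gene. SF3B1 mRNA did not differ detectably, at 76.1 ± 2.01 FPKM in K700E and 71.9 ± 1.65 in wild-type clones (SD, n = 2; limma adjusted p = 0.708). PHGDH, the enzyme of the first step of serine synthesis, was at 3.86 ± 0.56 FPKM in K700E and 16.0 ± 4.97 in wild-type clones, a log2 fold change of -1.78 ± 0.25 (SE) that missed the threshold in FPKM (limma adjusted p = 0.205). Counted by spliced reads, PHGDH fell by 2.19 ± 0.25 (SE) on the log2 scale, from 53.6 ± 15.5 to 11.7 ± 2.6 CPM (edgeR adjusted p = 0.0493). That edgeR call was lost without K700E1 (adjusted p = 0.114) or K700E2 (0.104). The next enzymes of the pathway had no call: PSAT1 was at 22.7 ± 2.43 and 21.1 ± 3.61 FPKM (spliced reads, edgeR adjusted p = 0.934) and SHMT2 at 80.3 ± 1.39 and 72.8 ± 15.3 (limma adjusted p = 0.758). PSPH was listed at 0 FPKM in 7 libraries and at 6.33 in 1 TWT1 library, although it had 1392 to 1484 spliced reads per clone. UQCC1 was at 13.3 ± 0.958 and 9.55 ± 1.06 FPKM (limma adjusted p = 0.417), with a log2 fold change of 0.43 in FPKM and -0.09 in spliced reads (edgeR adjusted p = 0.748).

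**Figure D4:**
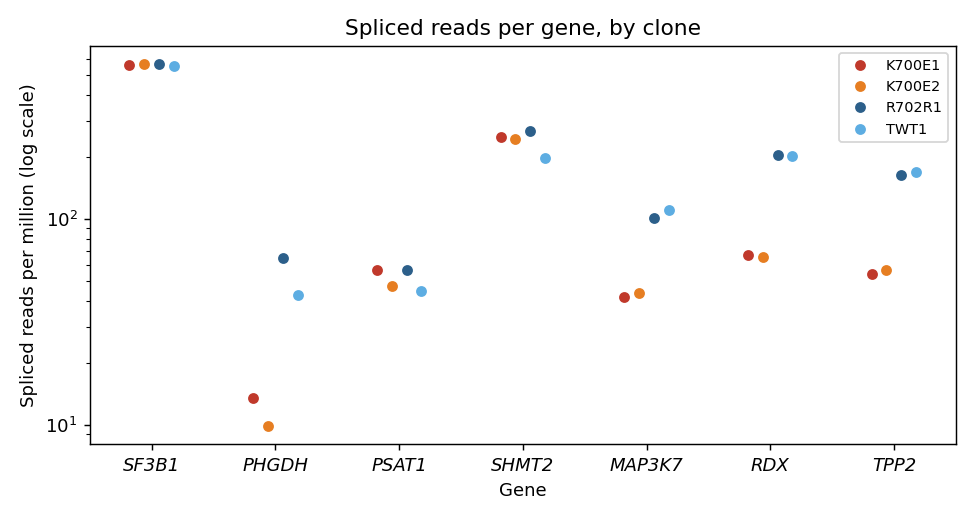
Spliced-read CPM (y axis, log scale) of named genes (x axis), 1 point per clone. For PHGDH, MAP3K7, RDX and TPP2 both K700E clones lie below both wild-type clones, while SF3B1 shows no such gap.

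In FPKM, limma called 40 of 11428 genes, 23 higher and 17 lower in K700E. Most of these calls rested on values of exactly 0, and only 3 of the 40 genes were above 0 in all 8 libraries. Of the 40 genes, 24 were listed at 0 in all 4 libraries of a genotype, 21 of those had spliced reads counted, and 19 of the 21 had at least 100 spliced reads in each clone of the genotype listed at 0. Thus ROMO1 was listed at 0 in every wild-type library and at 190.7 to 342 FPKM in K700E, while its spliced reads numbered 2843 to 3853 per clone in all 4 clones. Other protein-coding genes among those with the largest values were HIST2H3D, SELENOH, NDUFC1, CLDN7, ARFRP1, LGALS8, ODR4, ANKHD1 and MRPL27, all listed at 0 in wild type, and HIST2H3A, listed at 0 in 2 wild-type libraries. MRPL27 was also listed at 0 in 2 K700E libraries. SNRPN, WDR34, FOXRED1, SNX25, CGREF1 and CHTF18 were listed at 0 in K700E, and PPP4C, FDX2, ADORA2B and CHERP in 2 K700E libraries. For PPP4C, FDX2, ADORA2B and CHERP both K700E clones had a library at 0 and a library above 0. Averaging within a clone hid that disagreement from the test. In spliced reads, edgeR called the same direction for 3 of the 40, namely RDX, WDR34 and LINC01138, all singled out after their values were seen. ODR4, ANKHD1 and MRPL27 had spliced-read log2 fold changes of -0.03, -0.03 and -0.11. CLDN7 and CGREF1 had larger ones, 3.24 and -5.44, that missed the threshold (edgeR adjusted p = 0.0788 and 0.0789). RDX, which encodes the membrane linker radixin, was at 15.1 ± 0.099 FPKM in K700E and 44.0 ± 1.87 in wild type (limma adjusted p = 0.0337). UBE2L3, a ubiquitin-conjugating enzyme, was at 41.7 ± 1.72 and 103 ± 0.141 FPKM (limma adjusted p = 0.048) but had a spliced-read log2 fold change of -0.14 (edgeR adjusted p = 0.459). Among the 10029 genes above 0 in all libraries, limma called 0, with 1220 at an unadjusted p under 0.05, and limma called 0 without K700E1, K700E2, R702R1 or TWT1, with 656, 651, 1851 and 2000 genes at an unadjusted p under 0.05.

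Spliced reads summed per gene are given as another measure for that reason, and the genes named from it were chosen by the same rule after the values were seen. Of 12889 genes, edgeR called 39, 8 higher and 31 lower in K700E. The lower genes included WASHC5, a WASH complex subunit (fell by 1.65 ± 0.07 SE, log2), RDX (by 1.62 ± 0.07), the peptidase TPP2 (by 1.58 ± 0.07), TTI1, a TTT complex subunit for kinase stability (by 1.54 ± 0.13), and MAP3K7 (by 1.29 ± 0.08). Their edgeR adjusted p-values were 0.00926 for WASHC5, RDX and TPP2 and 0.0249 for TTI1 and MAP3K7. VAV3, CLCA2, SYT8, ABCA12 and MUT, which encodes methylmalonyl-CoA mutase, fell by 2.94, 1.99, 1.94, 1.40 and 1.46. The 8 higher genes were ITGA4, BBS5, ZNF100, ZNF426, GSTO2, LINC01138, LXN and HSD17B8. ITGA4, the integrin alpha 4 subunit, had 1122 and 588 reads in the K700E clones and 0 in both wild-type clones, at least 659-fold higher against a floor of 3 reads over the wild-type clones. BBS5 had 327 and 350 reads against 0, at least 261-fold higher by the same floor. ZNF100 had 162 and 90 reads against 0. GSTO2 went from 31 and 67 reads in wild type to 636 and 800 in K700E. In FPKM, GSTO2 and LXN were listed at 0 in all 8 libraries, and HSD17B8 in both K700E2 libraries and 1 TWT1 library. LINC01138 lies among duplicated sequence, so its reads are uncertain. The count and its direction depended on the clones: 5 higher and 4 lower without K700E1, 6 and 11 without K700E2, 75 and 103 without R702R1, and 166 and 83 without TWT1. DESeq2 called 56 higher and 75 lower.

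Genes with a called acceptor 10 to 30 nt upstream had slightly lower mRNA levels as a group. Their median log2 fold change in FPKM was -0.05 over 131 genes, 77 of them below 0, against a 95% range of -0.02 to 0.07 in 10000 random lists matched on expression (permutation p = 1e-04, the smallest these lists can give). In spliced reads the median was -0.08 over 138 genes (random lists -0.05 to 0.02, permutation p = 2e-04). Genes are not independent replicates, and the shift is far smaller than the 2-fold threshold for a single gene.

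None of the 19 gene lists that could be tested passed camera in FPKM, with 5 at an unadjusted p under 0.05, and fry and camera with an estimated correlation called 0. In serine synthesis and one-carbon metabolism (19 members tested) 0 genes were called over all genes and 1, PHGDH, adjusted over the list alone (camera adjusted p = 0.187, 0.919 with an estimated correlation). In spliced reads 13 of its 24 members lay above 0 and 11 below. ALDH1L2 had a spliced-read log2 fold change of 0.84 (edgeR adjusted p = 0.151), DLD -0.52 (0.129). DLD was listed at 0 FPKM in all K700E libraries and in 1 TWT1 library, despite 5201 to 9451 spliced reads per clone. Those zeros enter the FPKM tests of this list and of the TCA cycle. For complex III (14 members) 0 genes were called over all genes or the list alone (camera adjusted p = 0.158), with TTC19 at 0.38 and BCS1L at 0.36 in spliced reads (edgeR adjusted p = 0.235 and 0.335). For complex I (37 members, camera adjusted p = 0.158) the 1 call was NDUFC1, listed at 0 in wild type, and NDUFS1 was listed at 0 in 3 wild-type libraries. Among the reported SF3B1 genes (24 members, camera adjusted p = 0.528) 1 gene, ANKHD1, was called over all genes and 5, among them ANKHD1, DPH5, MAP3K7 and TTI1, adjusted over the list alone. DPH5 was listed at 0 in 2 wild-type libraries, and its log2 fold change was 1.06 in FPKM and -0.97 in spliced reads. In spliced reads 4 members fell, among them MAP3K7, PPP2R5A and TTI1, and none rose. The 22 glycolysis genes with spliced reads split into 19 below and 3 above 0, among them LDHA and GPI at -0.36 each and SLC2A1 at -0.31, none of them called, and the FPKM test missed the threshold (camera adjusted p = 0.0675). In spliced reads camera called glycolysis and the reported SF3B1 genes lower (adjusted p = 0.0102 each), and neither was called with an estimated correlation. Camera with an estimated correlation gave an adjusted p of 0.905 for every list tested in spliced reads, so it cannot tell these lists from the others. Both tests in spliced reads were added after seeing the data.

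Among the epithelial lists, luminal markers (8 members, camera adjusted p = 0.0702) included KRT8 at 0.63 and EPCAM at 0.41 on the log2 FPKM scale, none called. Basal markers (18 members, camera direction down, adjusted p = 0.58) included KRT14 at 2.92, PERP at 0.58, LAMA3 at 0.47 and SFN at -0.37, none called. KRT14 was listed at 0 in both TWT1 libraries and was at 0.18 in spliced reads, PERP was at -0.06 in spliced reads, and SFN was at 261 to 281 FPKM in K700E against 349 to 352 in wild type (limma adjusted p = 0.375). LAMA3 was at 295 FPKM in both R702R1 libraries and at 562 to 587 in all others. Mesenchymal and matrix genes (9 members, camera adjusted p = 0.264) included FN1 at 1.15 and SNAI2 at -0.47, and FN1 also differed within a genotype, at 136 and 132 FPKM in K700E1 and 365 and 363 in K700E2. NF-kB targets (17 members, camera adjusted p = 0.158) included CXCL1 at 0.68 and IL1B at 0.67, where clone R702R1 also stood apart, with IL1B at 41.3 and 42.7 FPKM against 115 to 136 in all other libraries. The remaining camera adjusted p-values were 0.58 for mitochondrially encoded mRNAs (3 members, MT-CO1 at 0.35), 0.943 for the TCA cycle (DLST at -0.54, SDHC at 0.55), 0.462 for the ATF4 response (ASNS at 0.49), 0.58 for U2 and branch point factors (SUGP1 at 0.67, SF3A3 at -0.31), 0.918 for nonsense-mediated decay factors (UPF3B at -0.44), 0.367 for p53 targets (GDF15 at 0.41, DDB2 at -0.34), 0.629 for proliferation (AURKA at 0.36, MKI67 at -0.32), 0.693 for interferon-stimulated genes (ISG15 at 0.56), 0.469 for cholesterol synthesis (MVD at 0.55) and 0.918 for heme and iron handling. In spliced reads SUGP1 was at 0.82 (edgeR adjusted p = 0.0323), short of the fold threshold. It was the only U2 factor at an adjusted p under 0.05 there, and 14 of the 20 members with spliced reads lay below 0. Hematopoietic markers had too few members past the filter for a test, and CD14 was at 0.0505 to 2.77 FPKM. The median, mean and camera direction differed in sign for the mitochondrially encoded mRNAs, TCA cycle, nonsense-mediated decay, p53 and basal lists. Leaving out R702R1 gave 5 called lists and leaving out TWT1 4.

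Clones of one genotype also differed from each other. In spliced reads 529 genes differed by at least 2-fold between K700E1 and K700E2 and 805 between R702R1 and TWT1, against 852 to 946 between clones of different genotype. For acceptor use, 97 and 114 acceptors differed by at least 20 percentage points within genotypes, against 255 to 295 between them. These are values with 1 clone on each side and no test.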

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

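Of the tests in this part, those of failed FPKM estimates and of absent mRNA were chosen after the result was seen.

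Among 105 groups of 4 libraries, 14 held a library far from the other 3, where chance gives about 1 in 20 for independent normal values. That rate does not hold here, since libraries come in same-clone pairs and many genes were named for their large FPKM changes. In K700E, LGALS8 was at 19.4 FPKM in K700E1 replicate 2 against 7.7 to 9.34 in the others, ANKHD1 at 10.5 against 7.73 to 7.94, and DDX42 at 23.4 against 0, all in that library. In K700E1 replicate 1, MT-ND6 was listed at 0 against 18.1 to 19.9, and PFKM was at 41.0 against 56.4 to 59.5. In K700E2 replicate 1, CEBPB was at 15.8 against 41.4 to 44.8, SMG6 was listed at 0 against 5.52 to 6.26, and TP53INP1 was at 3.35 against 1.75 to 1.9.

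In wild type, TWT1 replicate 1 had PSPH at 6.33 and NDUFS1 at 43.2 FPKM, both listed at 0 in the other 3 libraries, and DLD listed at 0 against 30.7 to 33.1. MT-ND6 was at 35.2 in TWT1 replicate 2 against 15.4 to 18.1. FOXM1 was at 20.6 in R702R1 replicate 2 against 0 in the others, and UROS was listed at 0 there against 16.8 to 20.2.

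Genes such as ROMO1, SELENOH and SNX25 were called in FPKM because a whole genotype was listed at 0. The tables argue against absent mRNA as the cause for most of the 21 such genes with spliced reads counted, whose median size of log2 fold change in spliced reads was 0.387 (quartiles 0.179 to 0.827), but not for CGREF1, with 2 and 22 reads in K700E against 509 and 714, and CLDN7 had 139 and 418 reads in wild type against 1881 and 2532. Of the 21, 90.5% had at least 100 spliced reads in each clone of the genotype at 0, which is consistent with failed FPKM estimates. The zeros did follow genotype among these clones: 30 tested genes were at 0 in all libraries of 1 genotype and above 0 in the other. The other pairings of clones gave 3 and 3 (exact binomial p = 9.2e-10). Genes are not independent trials, so this p-value does not measure the spread between clones. Why estimates would fail by genotype stays open, and a changed set of assembled transcripts in K700E is an untested hypothesis.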

How the results depend on the processing

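All of the alternatives for the spliced-read calls, the restriction to genes above 0 in all 8 libraries, annotated transcripts only, protein-coding genes only and camera on spliced reads and the reference site by mean use were chosen after seeing the data. The cause was not tested where none is named.

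Genes called in FPKM numbered 40 (23 higher, 17 lower). The count was 61 (37 higher) with a pseudocount of 0.1, 6 (5 higher, 1 lower) without the filter, 21 (12 and 9) at a mean of at least 5 FPKM, 91 (45 and 46) over 8 libraries, 69 (35 lower) with the clone as a random effect, 69 (42 and 27) in replicate 1 libraries alone and 70 (44 and 26) in replicate 2 libraries alone. Spliced reads gave 39 with edgeR (8 and 31, or 20.5% higher against 57.5%) and 131 with DESeq2 (56 and 75). Annotated transcripts alone gave 9 lower genes. Among genes above 0 in all 8 libraries limma called 0 (0 higher, 0 lower; 1220 at an unadjusted p under 0.05) and leaving out a clone gave 0 to 0. Of 39 genes called by edgeR in spliced reads, DESeq2 kept 39 among 131 and 8 libraries 39 among 236 (118 higher, 118 lower). Leaving out a clone gave 9 to 249, of which 3 were shared without K700E1, 11 without K700E2, 38 without R702R1 and 39 without TWT1. Lists called by camera numbered 0, against 3 with the clone as a random effect, 2 in spliced reads, 2 among genes above 0 in all libraries and 0 to 5 when a clone was left out.

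Acceptors called numbered 243, against 0 with limma on the log2 odds (3596 at an unadjusted p under 0.05), 656 with DESeq2, 407 over 8 libraries, 411 without a minimum change and 30 to 159 when a clone was left out. Donors called numbered 9, against 45 with a minimum of 1 read, 15 with 50 reads, 0 with limma (2404 unadjusted), 122 with DESeq2, 37 over 8 libraries, 36 without a minimum change and 1 to 16 when a clone was left out. A higher share of acceptors 10 to 30 nt upstream than of other acceptors was called higher in each alternative but limma on the log2 odds, which called 0. With the reference site by mean use over all clones, 249 acceptors (231 higher, 18 lower) and 9 donors (8 and 1) were called. The difference in cryptic share was 0.0651 points, 0.0648 with that reference, 0.0506 for donors with at least 100 reads in each library and 0.112 with annotated acceptors included. The ratio of K700E to wild type in these settings was 3.431, 3.435, 3.055 and 2.351, in that order.

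Among called genes named in the report, the direction turned for ODR4 (-0.03 in edgeR and -0.025 in DESeq2, on spliced reads), ANKHD1 (-0.026 and -0.021), MRPL27 (-0.112 and -0.107), PPP4C (0.004 in DESeq2) and UBE2L3 (0.063 with annotated transcripts alone). Of the other called genes, AC006329.1 (-0.15) and AC093484.3 (0.83) also had the other sign in spliced reads.

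Samples with one replicate number did not deviate together across genotypes (correlation of deviations -0.031 to 0.022), so the numbers do not pair them. With the replicate number as a block over 8 libraries, 76 genes (40 higher, 36 lower) were called in FPKM, 228 in spliced reads, 388 acceptors and 32 donors. Depth also limits single acceptors, since several named ones, such as ZNF548 and GCC2, have under 60 donor reads in at least 1 clone.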

Other observations

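Of the tests in this part, that of upstream acceptors in lower genes was chosen after the result was seen.

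Other genes called lower in spliced reads are given here, all chosen after their values were seen. LAMA1, a laminin chain, fell by 1.11 ± 0.09 (SE, log2) and COL6A3, a collagen VI chain, by 1.35 ± 0.11 (edgeR adjusted p = 0.0249 and 0.027, n = 2 clones each). KPNA1, a nuclear import adaptor, fell by 1.06 and TPR, a nuclear pore basket protein, by 1.05 (edgeR adjusted p = 0.0249 each). DNAJC3, a chaperone of the endoplasmic reticulum, and DLG1, a polarity scaffold, each fell by 1.32 (edgeR adjusted p = 0.0249 each).

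Of the 39 spliced-read calls 31 were lower in K700E, an excess that did not hold without K700E1 (5 higher, 4 lower), without TWT1 (166 and 83) or over 8 libraries (118 and 118). Uncalled genes matched to the 31 on junction number had a log2 fold change of -0.013 (mean over bins of the median), so such genes did not fall in general. This cannot decide whether junction number played a part in the calls. The matched genes numbered 6412 of 12889, and normalization centres most genes near 0. Gene length itself was not tested. Loss of chromosome regions is argued against, since uncalled genes within 2 Mb of the 31 had a median log2 fold change of 0.001. Of the 20 lower genes with a tested acceptor 10 to 30 nt upstream, 6 had a called one (ACD, MAP3K7, RDX, TPP2, TPR and TTI1), against 10.6% of other such genes (two-sided Fisher's exact p = 0.016). This is consistent with the hypothesis that cryptic acceptors lower some of these mRNAs. The 24 of 31 lower genes with no called acceptor or donor stay open.

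ITGA4 and BBS5 had no spliced read in the wild-type clones. Genes with 0 reads in both clones of a pair and at least 100 in each of the others numbered 2 for the genotype split and 0 for the other pairings (exact binomial p = 0.11). Single clones alone lacked reads of 1, 1, 0 and 3 such genes in K700E1, K700E2, R702R1 and TWT1. An effect of genotype and a difference between clones cannot be told apart here, because each genotype has only 2 clones. The binomial p-value counts genes and not clones.

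The 4 clones make 3 splits into pairs, too few for a share under 0.05, and in each case 1 split, the real one, gave the highest count. The real split gave 243 acceptors against at most 3, 40 genes in FPKM against at most 1, and 39 genes in spliced reads against at most 1.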
